A study of Rattus norvegicus with 12 samples.

How the data were processed

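RNA from rats with a thermal injury and from sham-treated rats was measured on Affymetrix RAE230A arrays 1, 2, 4 and 7 days after the injury, with 3 samples per day. The labels give each of the 12 samples as a pair of channels, sham in channel 1 and thermal injury in channel 2. They do not name the tissue or say whether the 3 samples of a day came from separate animals, so each p-value for a gene or probe set measures only the spread between samples. The values are log2 ratios of 2 array signals that the authors deposited, 1 value per probe set and sample. How the authors scaled the arrays, with which software, and which genome the probe sets were designed on are not given in the sources used here. The order of the ratio is not stated either. Injury over sham is likely, because the labels put injury in channel 2 and sham in channel 1, and a positive value is read as higher in the injured rats throughout. The direction of every change depends on that reading. For arrays, their number limits the precision.

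Each deposited ratio was searched for the pair of whole numbers whose log2 quotient it is, by continued fractions with a tolerance of 1e-09 and a cap of 20000. With numbers of at most 3000, between 66.3% and 69.4% of the ratios of an array were recovered, against between 0.220% and 0.358% of values shifted at random. The recovered numbers are signals in lowest terms, so they can be smaller than the original signals by a common factor. At most 0.170% of the recovered numbers were equal between 2 samples, so each ratio had its own injury signal and its own sham signal. The median over the 9 arrays of days 2, 4 and 7 of the smaller recovered signal, in log2 steps, served as the brightness of a probe set, with a median of 10.37.

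The recovered signals were then used to check that the same identifier stood for the same probe set in every array. They did not agree across arrays for day 1, as the results give in full. No gene is therefore named for day 1, and the planned results by gene that need day 1 were left out, which are day 1 itself, the mean of 4 days, the F test over 4 days, and days 2 and 7 minus day 1. The mean of days 2, 4 and 7, the F test over these 3 days with 2 degrees of freedom, and day 7 minus day 2 were put in their place after the data had been seen.

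Of the 15923 probe sets, 57 control probe sets were left out and 15866 were tested. Gene symbols came from the platform's own annotation. It gave 1 symbol to 12783 probe sets, several to 312 and none to 2771. Of these probe sets, 12748 had a gene ID in the GRCr8 reference table, which was used for names and for the genomic spans of genes and changed no symbol. Probe sets of 1 gene were averaged, which gave 10411 genes, 1868 of them with over 1 probe set. Each array was centred on its median, which lay between -0.13 and 0.16 before centring, and all changes are relative to that median.

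The fit planned before the data were examined was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per day over the 12 arrays, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. It is called the 12-array fit. It estimates the spread of each probe set over all 4 days, although the day 1 values under an identifier belong to other probe sets. A second fit, chosen after seeing the data, left out the 3 day 1 arrays and let the variance prior follow brightness (eBayes trend, 6 residual degrees of freedom). It is called the variance trend fit. Adjusted p for genes, probe sets and lists come from limma, and from the 12-array fit unless the other is named. Those for correlations over arrays are Benjamini-Hochberg adjusted exact permutation p.

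Both fits were tested on simulated data for the same 10411 genes, with 50 genes changed at each size. The simulated noise was independent between genes and had each gene's spread from the 12-array fit on all 4 days. Every change was equal on days 2, 4 and 7. The mismatch of the day 1 rows and correlation between genes were not simulated, so the shares recovered do not rank the 2 fits on the real data. For day 2, the 12-array fit recovered 0% of genes changed by a log2 of 0.5, 40% at 1, 66% at 2 and 98% at 4, with 3 false calls. The variance trend fit recovered 2%, 42%, 66% and 96%, with 4 false calls. For the mean of days 2, 4 and 7, the 12-array fit recovered 26%, 68%, 90% and 100% at the same sizes with 11 false calls, and the variance trend fit 22%, 66%, 86% and 100% with 12.

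The 33 gene lists were fixed before the data were examined. Because the labels name no tissue, 22 cover pathways, among them liver functions, and 11 cover markers of cell types and tissues that a sample could hold. Each list was tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Camera sets the members of a list against all other genes. Its p therefore depends on the number of members and on the correlation used, and does not measure the spread between samples alone. Adjustment was over the 33 lists within a comparison. Beside the count over all genes, members were also counted with p adjusted over the list alone. Genes to name were set before the data were examined. Per day they are the 10 highest and 10 lowest among genes past the threshold with the same sign in all 3 arrays, or, where none passed in a direction, the 5 with the smallest p, given as not passing. For the difference between days they are the 10 smallest p of the F test. For each list they are up to 2 passing members with the largest rise and 2 with the largest fall, or the 2 smallest p where none passed. Genes called by the variance trend fit were added after their values were seen.

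Other settings fixed before the data were examined were no centring, quantile normalization within each day, scaling to 1 median absolute deviation, 1 probe set per gene, leaving out the genes of largest residual variance or with a ratio of exactly 0, robust variance, array weights, a block for the sample number, each day fitted alone, both other list tests, and leaving out each sample in turn. Fits without day 1, the variance trend, and a filter at 512 steps of brightness (a log2 of 9) were added after seeing the data. A turn of every ratio was not run, since it mirrors every sign by construction, and an offset for linear ratios was not needed because the values are already logarithms. Figures and tables of values were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.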

Results

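The burn to sham ratio of RNA levels was measured in rats 1, 2, 4 and 7 days after a thermal injury, with 3 samples per day and 12 samples in all. Each sample gave 1 log2 ratio for each of 15923 probe sets. The design asks which genes the injury changed on each day and whether the change differed between days. Values are mean log2 ratios with the SD over the 3 samples of a day. A mean over the 9 samples of days 2, 4 and 7 has the standard error (SE) of the 12-array fit. The spread behind that SE and its adjusted p includes the mismatched day 1 values, so it is not the gene's own spread over the 9 samples.

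The identifiers of days 2, 4 and 7 stood for the same probe sets, and those of day 1 did not follow them. The rank correlation of the recovered signals across probe sets, which are not independent replicates, was between 0.681 and 0.723 for the 36 pairs of arrays among days 2, 4 and 7. It was between 0.676 and 0.685 for the 3 pairs within day 1, and between 0.00438 and 0.0292 for the 27 pairs of a day 1 array with another. The 18 spike-in probe sets, which measure RNA added in known amounts, had an SD between 0.116 and 0.236 within the arrays of days 2, 4 and 7 and between 1.00 and 1.14 within those of day 1. No shift, reversal or sorting of the identifiers that was tried raised the Pearson correlation of day 1 with the other days above 0.0855. At day 1, 443 of 15866 probe sets passed the threshold, 212 higher and 231 lower, and 2540 had an unadjusted p under 0.05. These calls used a spread pooled with values of other probe sets, and 0 passed in a limma fit of day 1 alone. No gene can be named for them.

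**Figure D1:**
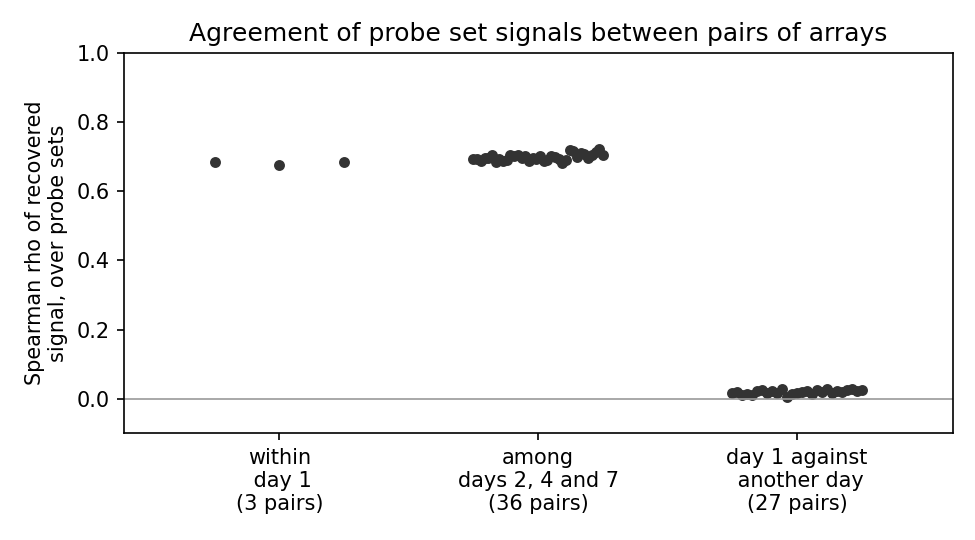
Rank correlation (Spearman's rho, no unit) of recovered signals across probe sets for each pair of arrays, grouped by whether both, one or neither array is from day 1. The 27 points that pair day 1 with another day lie between 0.00438 and 0.0292, and all other points lie at 0.676 or above.

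Over days 2, 4 and 7 together, 8 genes passed, of which 5 were higher after the injury, among them the acute-phase genes A2m and Orm1, and 3 were lower. Spink1, a trypsin inhibitor made by pancreas and liver, was 9.46-fold higher (log2 3.24, SE 0.34, adjusted p = 0.017). A2m, a protease inhibitor and the classical rat acute-phase protein, was 2.41-fold higher (log2 1.27, SE 0.16, adjusted p = 0.026). Orm1, another acute-phase protein, was 1.72-fold higher (log2 0.78, SE 0.09, adjusted p = 0.026). Spink1l was 1.79-fold higher and Pcolce, which aids the processing of procollagen, 1.78-fold higher. Akr7a3, an aldehyde-reducing detoxification enzyme, had a log2 ratio of -0.58 (SE 0.08, adjusted p = 0.04). Cdkn3, a phosphatase of the cell cycle, had -1.58 and the zinc finger gene Zfp37 -2.42. The sign was the same in 9 of 9 samples for 7 of the 8 genes, and in 8 of 9 for Cdkn3. The call of 8 genes among 10411, with 792 at an unadjusted p under 0.05, came down to between 0 and 5 when a single sample was left out. Without day 1 the fit called 4 genes, 3 of the 8 among them. With the variance trend, 34 genes were called, 16 higher and 18 lower, all 8 among them.

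Among the gene groups over these 3 days, the positive acute-phase proteins rose, with 20 of 26 members above 0 (median 0.10, adjusted p = 6.97e-06, and 0.191 with an estimated correlation). Adjusted over the list alone, 6 members rose and 0 fell, and over all genes 2 rose. Lcn2, an iron-sequestering acute-phase protein, was at 1.19. In the 12-array fit the acute-phase list passed at day 2 but not at day 4 (12 of 26 above 0, median -0.01, adjusted p = 0.463) or day 7 (13 of 26, median 0.04, adjusted p = 0.0643). All calls by day in this paragraph are from that fit, which called 6, 8 and 5 lists at days 2, 4 and 7. The variance trend fit called 8, 8 and 10 lists, all of those among them. At day 4 its 8 lists were the same, while a list given as not passing at day 2 or 7 can pass there. Complement and coagulation rose, with 25 of 31 members above 0 (median 0.11, adjusted p = 3.11e-05, and 0.217 with an estimated correlation) and 3 members rising adjusted over the list alone, among them C4bpa at 0.50 and Kng2l1 at 0.64. It too passed at day 2 in the 12-array fit but not at day 4 (median 0.09, adjusted p = 0.439) or day 7 (0.03, adjusted p = 0.0643). Phase II conjugation fell, with 28 of 36 members below 0 (median -0.16, adjusted p = 2.73e-05, and 0.102 with an estimated correlation) and 6 members falling adjusted over the list alone, among them the carboxylesterase Ces1d at -0.69 and the aldehyde oxidase Aox1 at -0.59. These named members do not conjugate. Despite its name, the list also holds such hydrolysing or oxidizing enzymes, namely Aldh1a1, Aox1, Ces1c, Ces1d, Ces2c, Ephx1 and Ephx2. This list passed at day 7 in the 12-array fit but not at day 2 (median -0.10, adjusted p = 0.0588) or day 4 (-0.06, adjusted p = 0.667). Cell cycle genes fell, with 27 of 39 below 0 (median -0.12, adjusted p = 8.45e-04, and 0.217 with an estimated correlation), and Cdkn3 and Cdk1, the latter at -0.68, were the 2 that passed adjusted over the list alone. Cell cycle genes passed at day 2 but not at day 4 (median -0.09, adjusted p = 0.0631) or day 7 (-0.04, adjusted p = 0.207). The exocrine pancreas list rose with 15 of 17 members above 0 (median 0.49, adjusted p = 2.97e-06, and 0.217 with an estimated correlation), and 5 members rose adjusted over the list alone, including Spink1 and Prss3b at 1.41. Its member Cela1 was lower, at -0.46, and was called by the variance trend fit (adjusted p = 0.034) but not by the 12-array fit (0.74). This list passed at day 4 but not at day 2 (8 of 17 above 0, median -0.03, adjusted p = 0.955) or day 7 (10 of 17, median 0.13, adjusted p = 0.625), and its medians in samples 2 and 3 of day 4 were 3.01 and 1.75. Haemoglobin and red cell genes had 8 of 8 above 0 (median 0.23, adjusted p = 0.0324, and 0.191 with an estimated correlation), with Ahsp at 0.54 and Hbb at 0.27, neither passing. Cholesterol synthesis had 17 of 21 below 0 (median -0.09, adjusted p = 0.0499, and 0.79 with an estimated correlation), with Lss at -0.42 and Msmo1 at -0.29, neither passing. The cholesterol call ended in 5 and the haemoglobin call in 4 of the 9 fits that left out a sample, and the cholesterol call also ended without day 1 (adjusted p = 0.0957) and in the variance trend fit (0.082).

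**Figure D2:**
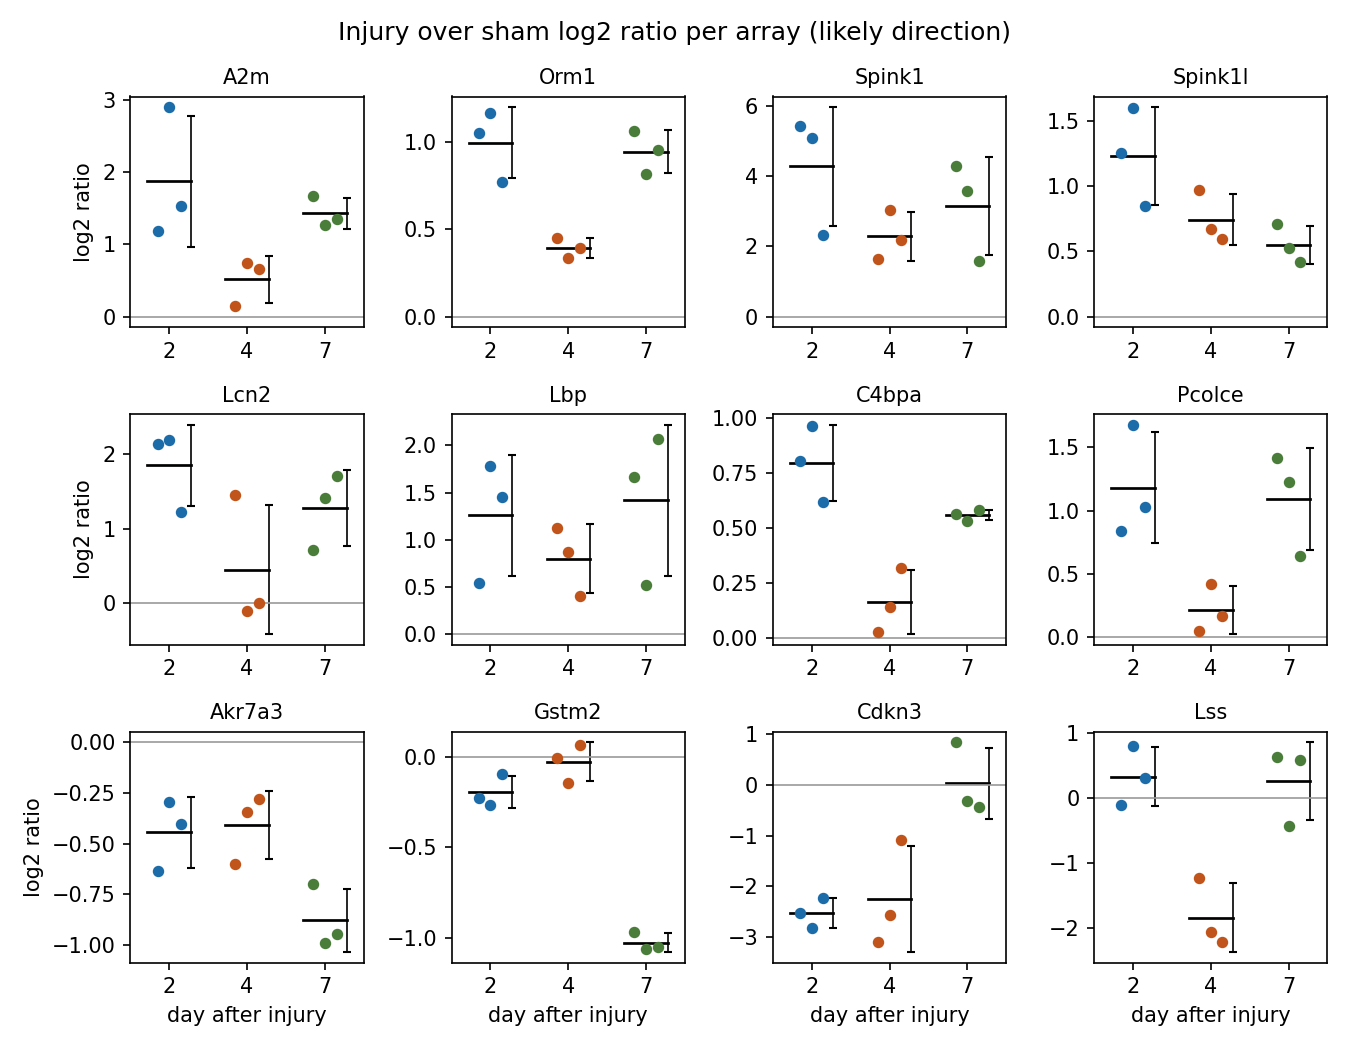
Log2 ratio of injury to sham (vertical axis) at days 2, 4 and 7 for 12 named genes, 1 panel per gene. Points are samples, the line is the mean and the bar the SD of 3 samples. A2m, Orm1, Spink1, Spink1l and Pcolce lie above 0 and Akr7a3 below 0 in all 9 samples.

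At day 2, most members of the acute-phase and lipid synthesis lists had ratios above 0, and none of the 6 list calls of that day held with an estimated correlation. The positive acute-phase proteins rose, with 24 of 26 members above 0 (median 0.26, adjusted p = 2.5e-09, and 0.156 with an estimated correlation). A2m was at 1.87 ± 0.91 (SD, n = 3; 3.65-fold) and Lcn2 at 1.85 ± 0.54, and 5 members rose adjusted over the list alone. Complement and coagulation rose, with 26 of 31 above 0 (median 0.22, adjusted p = 1.07e-05, and 0.259 with an estimated correlation), led by C4bpa, which binds complement C4b, at 0.79 ± 0.17, the 1 member that passed adjusted over the list alone. Fatty acid and triglyceride synthesis rose, with 21 of 27 above 0 (median 0.29, adjusted p = 1.27e-04, and 0.259 with an estimated correlation), and Cd36, a fatty acid transporter at the cell surface, was the 1 member passing adjusted over the list alone, at 1.98 ± 0.36. Cholesterol synthesis rose with 20 of 21 above 0 (median 0.24, adjusted p = 8.58e-04, and 0.375 with an estimated correlation), with Ebp at 0.72 and Fdps at 0.38, neither passing. The bile acid and transporter list rose with 22 of 30 above 0 (median 0.19, adjusted p = 0.00837, and 0.259 with an estimated correlation), with the nuclear receptors Nr0b2 at 1.03 and Hnf4a at 0.53, neither passing. Cell cycle genes fell, with 25 of 39 below 0 (median -0.16, adjusted p = 0.0182, and 0.397 with an estimated correlation), and Cdkn3 fell adjusted over the list alone. The cell cycle call ended without sample 1 (adjusted p = 0.068) or 3 (0.151), the bile acid call without sample 2 (0.086) or 3 (0.053), and the cholesterol call without sample 3 (0.072).

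By gene, day 2 had 0 calls among 10411 genes and 0 among 15866 probe sets in the 12-array fit (limma), with 654 genes and 1089 probe sets at an unadjusted p under 0.05. The 5 higher genes with the smallest p, none passing, were Spink1 at 4.28 ± 1.70, Mmp14, a matrix metalloproteinase, at 1.10 ± 0.05, A2m, Spink1l at 1.23 ± 0.38 and Orm1 at 1.00 ± 0.20. The 5 lower ones, none passing, were Ciao3 at -1.74 ± 0.21, Cdkn3 at -2.52 ± 0.29, Ces1d at -1.35 ± 0.35, Ank2 at -2.15 ± 0.76 and Tmem38b at -0.90 ± 0.23 (SD, n = 3 for each). Adjusted p for these 10 lay between 0.078 and 0.12. The variance trend fit called 15 genes at day 2, of which 12 rose and 3 fell. Those that rose included Spink1, A2m, Mmp14, Spink1l and Orm1, the phosphatase Dusp1 at 1.37 ± 0.62, the insulin-like growth factor binding protein Igfbp1 at 2.34 ± 1.12, the cytochrome P450 Cyp2c12 at 3.63 ± 1.99 and the lipoprotein gene Apob at 0.70 ± 0.12. C4bpa, Cd36 and the coagulation inhibitor Serpina10 at 0.73 ± 0.28 completed the 12. Ciao3, Ces1d and Prkaa2, a subunit of AMP-activated kinase at -1.14 ± 0.40, fell. Without sample 2 the variance trend fit called 0 genes at day 2, and without sample 1 it called 8.

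At day 4, most members of the respiratory chain, ribosomal and exocrine pancreas lists had ratios above 0 and most of the cholesterol synthesis list below 0, and none of the 8 list calls of that day held with an estimated correlation. The mitochondrial respiratory chain rose, with 72 of 78 members above 0 (median 0.31, adjusted p = 6.53e-14, and 0.147 with an estimated correlation), as in Atp5if1, an inhibitor of ATP synthase, at 1.83 ± 0.63 and Ndufa2 at 0.69 ± 0.12, neither passing alone. Cytosolic ribosomal proteins rose, with 37 of 40 above 0 (median 0.31, adjusted p = 1.58e-07, and 0.147 with an estimated correlation), with Rpl37a at 1.00 and Rps29 at 0.59, neither passing. The actin probe sets nearer the 3′ end of the message differed from those nearer the 5′ end by -0.35, 0.38 and 0.23 in samples 1 to 3 of day 4, and those of GAPDH by 0.14, 0.31 and -0.08, on the log2 scale. Cholesterol synthesis fell, with 19 of 21 below 0 (median -0.31, adjusted p = 4.59e-08, and 0.147 with an estimated correlation), and 5 members fell adjusted over the list alone. Among them were Lss, which closes the sterol ring, at -1.84 ± 0.53 and Sqle, squalene epoxidase, at -1.15 ± 0.26. Proteasome and ubiquitin genes rose, with 30 of 35 above 0 (median 0.21, adjusted p = 0.00493, and 0.271 with an estimated correlation), with Psma1 at 0.51 and Psmc5 at 0.31, neither passing. Haemoglobin and red cell genes had a median of 0.58 (6 of 8 above 0, adjusted p = 0.0366, and 0.147 with an estimated correlation; Hbb at 0.59 and Alas2 at 0.57, neither passing), and macrophage markers 0.18 (13 of 16 above 0, adjusted p = 0.0366, and 0.675 with an estimated correlation; Tyrobp at 0.57 and Clec4f at 0.34, neither passing). Circadian clock outputs fell, with 11 of 16 below 0 (median -0.36, adjusted p = 0.022, and 0.147 with an estimated correlation), and Bhlhe40 at -0.70 fell adjusted over the list alone. The haemoglobin call ended without any 1 of the 3 samples (adjusted p = 0.068 to 0.127), the macrophage call without sample 1 (0.078) or 2 (0.339), the circadian call without sample 1 (0.134) or 3 (0.101), and the proteasome call without sample 2 (0.068).

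The exocrine pancreas list had the highest median of the lists at day 4. Of its 17 members, 16 were above 0 (median 1.84, adjusted p = 4.23e-16, and 0.147 with an estimated correlation), and 13 rose adjusted over the list alone. The digestive enzyme genes Cpa1, a carboxypeptidase, and Amy2a3, an amylase, were at 3.52 ± 1.51 and 3.26 ± 2.81. The list median was 0.10 in sample 1, 3.01 in sample 2 and 1.75 in sample 3. Pnliprp1, a pancreatic lipase-related gene, was the 1 gene of 10411 that passed over all genes at day 4, 5.65-fold higher (SD of the log2 ratio 0.33, n = 3, adjusted p = 0.022), and its probe set was the 1 of 15866 that passed. In limma's 12-array fit 731 genes and 1073 probe sets had an unadjusted p under 0.05. The Pnliprp1 call ended without sample 1 (adjusted p = 0.107) or 2 (0.319) and in a fit without day 1, which called 0 genes. Without sample 3 the 12-array fit called 5 genes. At day 4, 0 genes were called by the variance trend fit, with 1112 at an unadjusted p under 0.05, and it called 3 without sample 1, 6 without sample 3 and 36 with array weights. The 5 lower genes with the smallest p, none passing, were Lss, Cdkn3 at -2.25 ± 1.05, Zfp37 at -3.62 ± 0.65, the hyaluronidase Hyal3 at -1.11 ± 0.26 and Rcan1 at -0.97 ± 0.32.

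**Figure D3:**
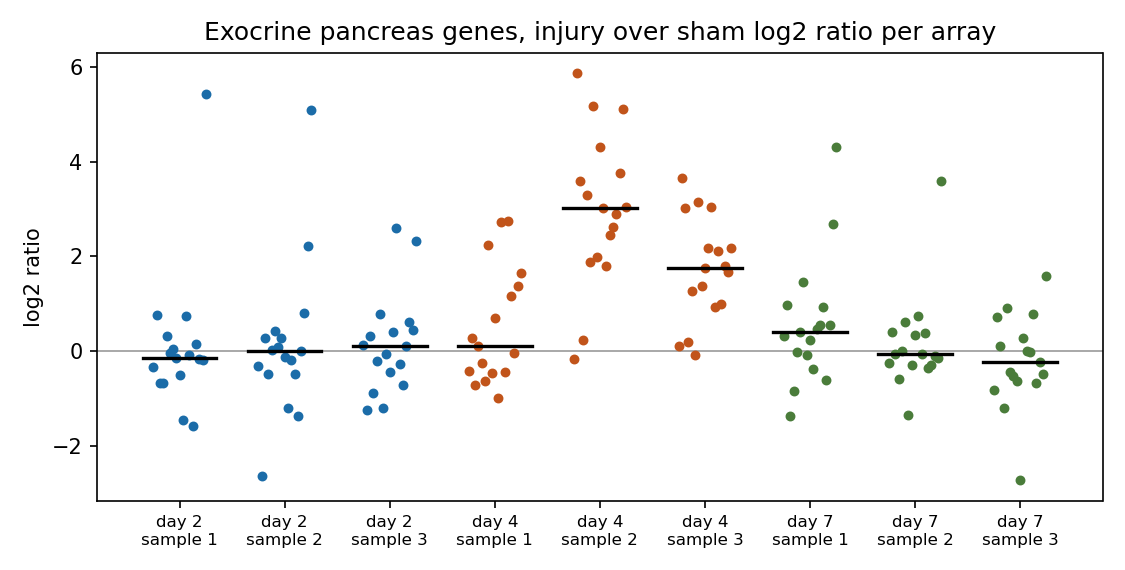
Log2 ratio of injury to sham (vertical axis) of the 17 exocrine pancreas genes in each of the 9 samples of days 2, 4 and 7. Points are genes and lines are list medians, which are 0.10, 3.01 and 1.75 in samples 1 to 3 of day 4 and between -0.23 and 0.40 in the other 6 samples.

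At day 7, 5 lists fell after the injury, and the calls of phase II conjugation and of the stellate cell and matrix list held with an estimated correlation. That estimate includes the mismatched day 1 rows, so whether these calls hold without them is not known. Phase II conjugation fell, with 29 of 36 members below 0 (median -0.42, adjusted p = 5.45e-06, and 0.0346 with an estimated correlation). The glutathione transferase Gstm2, at -1.03 ± 0.05, was the 1 member that fell adjusted over the list alone. The stellate cell, fibroblast and matrix list fell, with 26 of 34 below 0 (median -0.18, adjusted p = 0.00119, and 0.0346 with an estimated correlation), and Tagln, an actin-binding protein of smooth muscle, fell adjusted over the list alone at -2.12 ± 0.34. The respiratory chain fell, with 72 of 78 below 0 (median -0.27, adjusted p = 2.42e-08, and 0.244 with an estimated correlation). Its members Ndufa7 at -0.72 ± 0.10 and Sdha at -0.61 ± 0.35 did not pass adjusted over the list alone. The actin 3′ minus 5′ difference was -0.88, -0.44 and -0.88 in samples 1 to 3 of day 7, and that of GAPDH -0.39, -0.21 and -0.80. Cytochrome P450 genes fell, with 28 of 36 below 0 (median -0.25, adjusted p = 0.00576, and 0.244 with an estimated correlation). The 2 with the smallest p, Cyp1a1 at 2.27 ± 1.35 and the nuclear receptor Nr1i3 at -0.69 ± 0.19, did not pass and had opposite signs. Urea cycle and amino acid catabolism had 33 of 45 below 0 (median -0.18, adjusted p = 0.0476, and 0.498 with an estimated correlation), with Gpt at -0.83 and Cth at -0.45, neither passing. The urea call ended without sample 1 (adjusted p = 0.102) or 3 (0.376), and the P450 call without sample 2 (0.058), while 11 lists in place of 5 passed without sample 1.

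By gene, Dmap1, a binding partner of DNA methyltransferase, fell at day 7 in the 12-array fit, at -2.91 ± 0.46 (SD, n = 3; adjusted p = 0.042), the 1 call among 10411 genes with 945 at an unadjusted p under 0.05. Of 15866 probe sets 3 passed (adjusted p = 0.0262 for each, 1509 with an unadjusted p under 0.05), that of Dmap1 and 2 without a gene symbol, of which one was higher at 1.63 ± 0.22 and the other lower at -1.51 ± 0.19. The Dmap1 call ended without sample 1 (adjusted p = 0.096) or 3 (0.154) and in a fit without day 1, which called 0 genes. Without sample 2 the number of genes called was 19. The 5 higher genes with the smallest p, none passing, were the lens crystallin Crygd at 2.33 ± 0.21, the adrenergic receptor Adra2a at 2.62 ± 1.04, Lrrc51 at 1.43 ± 0.47, hepatocyte growth factor Hgf at 1.67 ± 0.21 and Orm1 at 0.95 ± 0.12. At day 7, 5 genes were called by the variance trend fit. Orm1 and Apob, the latter at 0.86 ± 0.17, rose. Gstm2, Akr7a3 at -0.88 ± 0.16 and Ndufa7 fell. Without sample 3 it called 0 genes, without sample 1 it called 1, and without sample 2 it called 12.

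**Figure D4:**
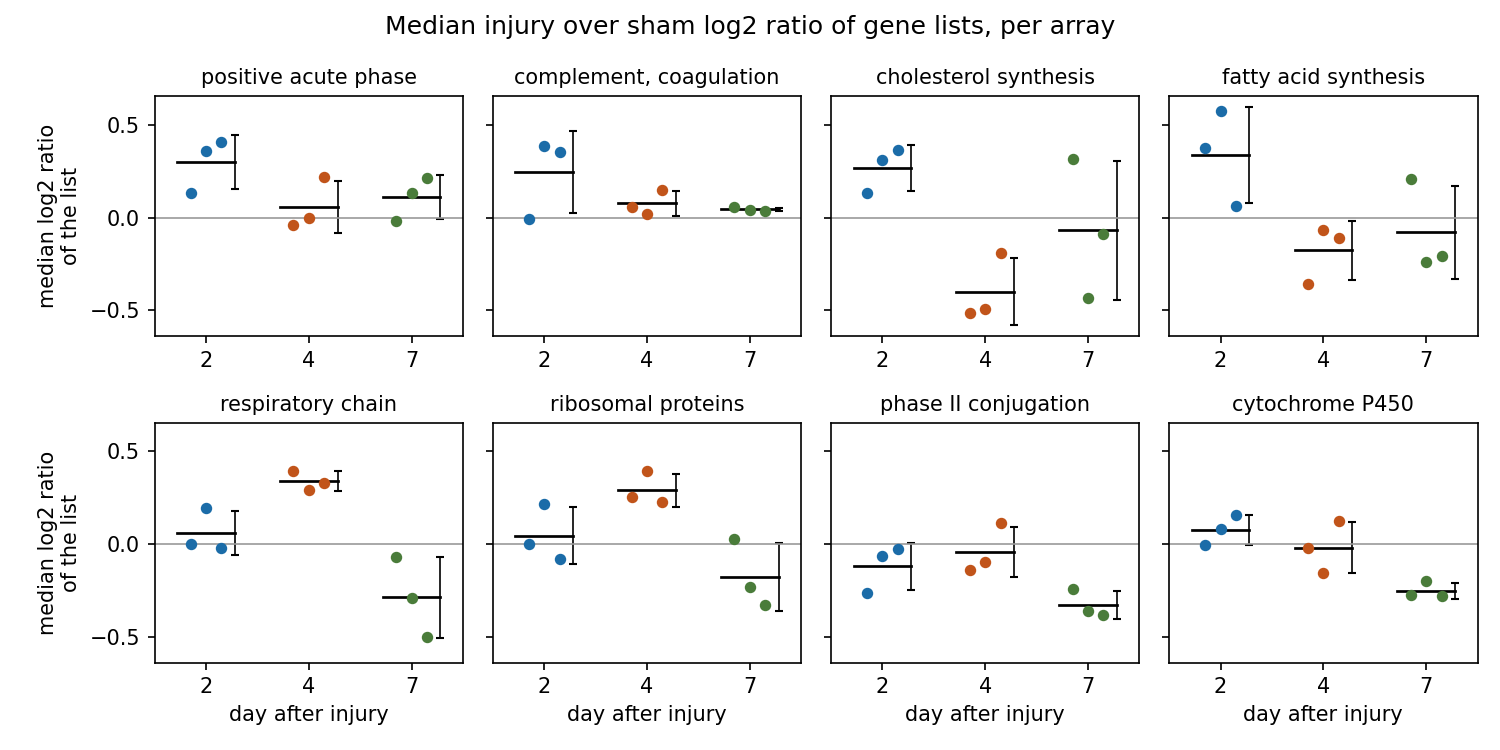
Median log2 ratio of injury to sham (vertical axis) at days 2, 4 and 7 for 8 gene lists, 1 panel per list. Points are the list median of each sample, the line is the mean of 3 such medians and the bar their SD. The respiratory chain lies between 0.29 and 0.40 in the samples of day 4 and between -0.50 and -0.07 in those of day 7.

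Between days, lists of lipid synthesis, the respiratory chain and the exocrine pancreas differed by camera at the preset correlation. From day 2 to day 4, cholesterol synthesis fell, with 21 of 21 members lower (median -0.59, adjusted p = 1.06e-10, and 0.143 with an estimated correlation), and Lss at -2.17 and Sqle at -1.71 were among the 4 that fell adjusted over the list alone. Fatty acid and triglyceride synthesis fell (median -0.44, 18 of 27 lower, adjusted p = 3.76e-05, and 0.181 with an estimated correlation), with Acacb, which makes malonyl-CoA, at -1.73 and Elovl5 at -0.97. The exocrine pancreas list rose by a median of 1.47 (16 of 17 higher, adjusted p = 6.93e-09, and 0.181 with an estimated correlation), with Amy2a3 at 4.30 and Cpa1 at 3.88, and Pnliprp1 rose by 3.72 (adjusted p = 0.014), the 1 gene called of 10411. From day 4 to day 7, the respiratory chain fell, with 72 of 78 lower (median -0.63, adjusted p = 7.18e-18, and 0.156 with an estimated correlation) and 12 members falling adjusted over the list alone, among them Ndufa3 at -1.41 and Ndufa7 at -1.27. Phase II conjugation fell (median -0.38, adjusted p = 0.00735, and 0.204 with an estimated correlation), and Gstt2 at -1.18 and Gstm2 were the 2 members that fell adjusted over the list alone. The phase II call ended without sample 3 of day 4 (adjusted p = 0.121). The exocrine pancreas list fell (median -1.76, 16 of 17 lower, adjusted p = 1.56e-07, and 0.241 with an estimated correlation), with Cpa1 at -3.66 and Ctrb1 at -2.96. From day 2 to day 7, the stellate cell and matrix list fell (median -0.20, 28 of 34 lower, adjusted p = 3.71e-04, and 0.0447 with an estimated correlation), with Tagln at -2.58 and Mmp14 at -1.17. The estimated correlation again includes the mismatched day 1 rows. In all, 10 lists differed between days 4 and 2, 7 between days 7 and 4, and 14 between days 7 and 2, and apart from the stellate list no call held with an estimated correlation (adjusted p between 0.143 and 0.373, 0.156 and 0.601, and 0.183 and 0.39).

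By gene, the F test over days 2, 4 and 7 called 0 of 10411 genes in limma's 12-array fit, with 844 at an unadjusted p under 0.05. The 10 genes with the smallest p were Pnliprp1 (adjusted p = 0.0538) and Dmap1, Bhlha15, Ciao3, Dusp1, Tnr, Lss, Hgf, Bag6 and Atf2 (0.242 each). The variance trend fit called 1 gene, Apob, the protein of very low density lipoprotein, at 0.70 ± 0.12 on day 2, -0.42 ± 0.02 on day 4 and 0.86 ± 0.17 on day 7 (SD, n = 3; adjusted p = 0.049), and in 6 of the 9 fits that left out a sample it called 0 genes. The 12-array fit called 0 genes for day 7 minus day 4 (964 at an unadjusted p under 0.05) and 0 for day 7 minus day 2 (639). The variance trend fit called 0 genes for day 4 minus day 2 (902), 0 for day 7 minus day 2 (867) and 3 for day 7 minus day 4, Apob at 1.28, Ndufa7 at -1.27 and Gstm2, which fell by 1.00 on the log2 scale. That count was 0 in 4 of the 6 fits that left out a sample of those days, 5 without sample 3 of day 4 and 24 without sample 2 of day 7. Pnliprp1, the 1 gene called for day 4 minus day 2, was called in 1 of the 6 fits that left out a sample of those days and was not called without day 1.

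Across the 10411 genes, which are not independent replicates, the mean ratios of day 2 correlated with those of day 4 at r = 0.0258 (rho = 0.0326) and with those of day 7 at r = 0.108 (rho = 0.0968), and days 4 and 7 at r = -0.0451 (rho = -0.0770). Between 2 samples of the same day, the ratios correlated across probe sets, before any averaging by gene, at r between 0.00271 and 0.148. Among the 7865 genes of higher brightness, the correlations were 0.0669, 0.177 and -0.0801.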

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

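The tests of day 1, of the injury at day 4 and of RNA integrity were chosen after the results were seen, as were day 7 minus day 2 and the variance trend fit. Each list below was picked out because its injury effect differed between 2 days by limma's camera, and each gene because it differed by limma.

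The first pattern is that the day 1 identifiers do not name the same probe sets as the others. Arrays of day 1 correlated with one another at a rho of at least 0.676, which argues against noise as the cause of the mismatch. With the other days they correlated at 0.0292 at most. That argues against an injury effect as the cause of the mismatch, since the signals of sham rats are part of both. Whether the injury changed expression on day 1 is not addressed by these correlations. A table of day 1 values in another order, or from another array design, is consistent with these values. The 443 probe sets that passed at day 1, picked out because they lie outside the comparisons by gene, therefore carry no names. No biological explanation was tested further.

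The second pattern is the exocrine pancreas list at day 4, with a median of 1.84. Noise of dim probe sets is argued against, as 0% of random lists of like brightness had a median as high. Pancreatic tissue in the samples may be the source, but 18 further acinar genes had a median of 0.12 (spread 0.11, and -0.08, 0.58 and -0.15 in samples 1 to 3), with 6.06% of matched random lists as far, and 19 islet genes a median of -0.10 (spread 0.13). Of the 18 acinar genes, 10 were above 0, and members differed. Ctrc (-0.205, 2.26 and 0.73 in samples 1 to 3) and Cuzd1 (0.162, 1.496 and 0.923) were highest in sample 2, like the pancreas list. Klk1 (-0.815, -0.0992 and -0.235) and Dmbt1 (-0.122, -0.195 and -0.422) were below 0 in each sample. Prss2 and Pdia2 were dim, at a brightness of 4.087 and 4.755. Both medians lie below the 0.2 set beforehand as the value that would argue against pancreatic tissue, so that rule was met. The acinar median lies below it by less than its spread, and Ctrc and Cuzd1 went with the list. The spread comes from resampling the genes of a list, not the samples, and was not part of the rule. Tissue carried over at dissection thus cannot be separated from an injury effect in the sampled tissue, for which the lowest sample stood at 0.10. How many of the 17 genes the sampled tissue itself expresses is open, as the labels name none.

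The third pattern is the respiratory chain list, high at day 4 and low at day 7, with the ribosomal list, high at day 4. At day 7 the ribosomal list did not pass in the planned fit (median -0.18, adjusted p = 0.0643, and 0.508 with an estimated correlation). By camera at the preset correlation it fell in the fit without day 1 (adjusted p = 0.00544) and in the variance trend fit (0.00229). Short span and brightness are argued against as the whole cause for the respiratory chain, since 0% of random lists matched on both were as far at day 4 (random median 0.12 against 0.31) and 0% at day 7 (-0.14 against -0.27), and for the ribosomal list at day 4 (0.12%) but not at day 7 (43.9%). RNA integrity or labelling length could account for part of it. Over the 9 arrays the actin 3′ minus 5′ difference went with the respiratory chain median at r = 0.658 (exact permutation p = 0.0552, two-sided, rho = 0.683, p = 0.0503). It did so at 0.484 without the 2 farthest arrays and at -0.113 within days (exact permutation within days, p = 0.77). GAPDH, added afterwards, gave r = 0.770 (exact permutation p = 0.0149, rho = 0.733, p = 0.0311), 0.495 and 0.318 (within days, p = 0.59). The permutations over 9 arrays ignore the days, so their p treat the arrays of a day as independent. The 4 relations computed, the ribosomal list included (r = 0.649 and 0.722), had exact permutation p adjusted to between 0.0548 and 0.0624, so that RNA integrity and an effect of the injury that turned between days 4 and 7 cannot be told apart, the latter untested.

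From day 2 to day 4, the median effect changed by -0.29 for positive acute-phase proteins, -0.22 for complement and coagulation, -0.44 for fatty acid and triglyceride synthesis, -0.59 for cholesterol synthesis, -0.15 for bile acid synthesis and transporters, -0.16 for the growth hormone axis, 0.25 for the respiratory chain, 0.22 for ribosomal proteins, -0.71 for circadian outputs and 1.47 for the exocrine pancreas. None of these 10 calls held with an estimated correlation, where the adjusted p lay between 0.143 and 0.373. Without sample 2 or 3 of day 2, the complement call ended (adjusted p = 0.252 and 0.137), as it did without sample 2 of day 4 (0.0583). The growth hormone call ended without sample 3 of day 2 (0.144) or sample 2 of day 4 (0.172), and the ribosomal call without sample 3 of day 2 (0.144). Pnliprp1 rose by 3.72.

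From day 4 to day 7, the median effect changed by 0.23 for cholesterol synthesis, -0.38 for phase II conjugation, -0.27 for proteasome and ubiquitin, -0.63 for the respiratory chain, -0.48 for ribosomal proteins, 0.76 for circadian outputs and -1.76 for the exocrine pancreas. None of these 7 calls held with an estimated correlation, where the adjusted p lay between 0.156 and 0.601. The cholesterol call ended without sample 1 of day 4 (adjusted p = 0.124) or of day 7 (0.312), the phase II call without sample 3 of day 4 (0.121), the proteasome call without sample 3 of day 7 (0.0583), and the circadian call without sample 1 or 3 of day 4 or sample 2 of day 7 (0.0523 to 0.093). In the variance trend fit Apob changed by 1.28 and Ndufa7 by -1.27, and Gstm2 fell by 1.00, and the number of genes called was 0 in 4 of the 6 fits that left out a sample, 5 without sample 3 of day 4 and 24 without sample 2 of day 7.

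From day 2 to day 7, the median effect changed by -0.22 for positive acute-phase proteins, -0.23 for negative acute-phase and other secreted proteins, -0.21 for the urea cycle, -0.17 for fatty acid oxidation, -0.36 for fatty acid synthesis, -0.35 for cholesterol synthesis, -0.35 for bile acid synthesis, -0.28 for cytochrome P450, -0.22 for phase II conjugation, -0.16 for oxidative stress defence, -0.31 for the respiratory chain, -0.23 for ribosomal proteins, -0.20 for stellate cells and matrix and -0.31 for endothelium. With an estimated correlation the stellate call held (adjusted p = 0.0447) and the others did not (0.183 to 0.39). Of the 6 fits that left out a sample, the phase II call ended in 5 (adjusted p = 0.052 to 0.14). In 4 of them ended the calls of positive acute-phase (0.0667 to 0.0913) and negative acute-phase proteins (0.0831 to 0.198), the urea cycle (0.0532 to 0.17), fatty acid oxidation (0.0913 to 0.352), oxidative stress defence (0.0763 to 0.155) and endothelium (0.051 to 0.0971). The fatty acid synthesis (0.0522 to 0.0913) and ribosomal calls (0.125 to 0.251) ended in 3, and the cholesterol (0.153) and bile acid calls (0.0818) in 1. Leaving out 1 sample left between 5 and 16 lists, with 6 without sample 2 of day 2, 9 without sample 3 of day 2, 5 without sample 2 of day 7 and 9 without sample 3 of day 7.

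Splits of the 9 arrays into 3 groups of 3 tested the difference between days, 100 drawn of 280. The F test of the 12-array fit called 0 genes, so that 100 of 100 splits gave as many and chance cannot be excluded, and the highest other split gave 5. In the variance trend fit the real days gave 1 gene, at an adjusted p of 0.049, and the highest other split 0, so that 1 of 100 splits gave as many. That share cannot exclude chance, because the count rests on 1 gene near the threshold. The count is 0 with no centring, with robust variance, with the block for sample number and in 6 of the 9 fits that left out a sample, for which no splits were run. For 2 days at a time, the 10 splits are too few for a share under 0.05. For day 4 minus day 2 the real split gave 1 gene against 1 in the highest other, 0 against 0 with the variance trend, and 10 lists against 7, which 2, 10 and 1 of the 10 splits reached. For day 7 minus day 4 it gave 0 genes against 1, 3 against 0 with the variance trend, and 7 lists against 6, and for day 7 minus day 2 it gave 0 genes against 0 in both fits and 14 lists against 8.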

How the results depend on the processing

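The fits without day 1, with the variance trend or with a brightness filter, and all alternatives to the variance trend fit, were chosen after seeing the data. Of 72 results for a named gene and 57 for a list, none reversed its sign in the alternatives where it was computed, including the leaving out of samples. Leaving out the genes of largest residual variance covered 57 gene and 51 list results, and the bright genes 55 and 55. A kept sign is little support, since these results were picked for a small p or for passing in the same data. Of the 57 list calls, 54 were lost with an estimated correlation and 44 with fry. Where counts moved, the cause was not tested, except that fits with fewer arrays or genes differ by construction. Between days, residuals correlated across genes at -0.0410 to 0.0682 for equal sample numbers (9 pairs) and -0.122 to 0.106 for unequal ones (18 pairs). This shows no link between equal numbers but cannot exclude one. Even 2 samples of the same day had ratios that correlated across probe sets at only 0.00271 to 0.148. Brightness limits the dim genes, whose ratios rest on small signals.

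In the order day 2, day 4, day 7, mean of days 2, 4 and 7, day 4 minus 2, day 7 minus 4, the 12-array fit called 0, 1, 1, 8, 1 and 0 genes, and the variance trend without day 1 called 15, 0, 5, 34, 0 and 3, with 1 by the F test and 10 lists at day 7. Leaving out the genes of largest residual variance gave 11, 5, 24, 35, 5 and 13, with 15 by the F test, 821, 21, 10 and 74 probe sets at days 1, 2, 4 and 7, 5 lists at day 4 and 9 for day 7 minus 2. Without day 1, days 4 and 7 and day 4 minus 2 gave 0 genes, the mean 4, and days 4 and 7 gave 0 and 1 probe sets. Bright genes without day 1 gave 4 genes at day 2, 0 at day 4, 0 for day 4 minus 2 and 5 lists at day 4. Scaling to 1 median absolute deviation gave 6 genes at day 2, 0 at day 7, 16 for the mean, 1 by the F test, and 248, 4 and 14 probe sets at days 1, 4 and 7. Array weights gave 4 genes at day 4, 2 at day 7, 20 for the mean, 2 for day 7 minus 4, 1 by the F test, and 153, 5 and 12 probe sets at days 1, 4 and 7. The block for sample number gave 0 genes at day 4, 1 for the mean, 0 for day 4 minus 2, 2 for day 7 minus 4, and 280 and 0 probe sets at days 1 and 4. Each day alone gave 0 probe sets at days 1, 4 and 7 and 0 genes at days 4 and 7. Robust variance gave 0 genes at day 7, quantile normalization 1 gene by the F test and 2 and 17 probe sets at days 4 and 7, and no centring 0 and 10.

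Within the variance trend fit, array weights gave 36 genes at day 4, 2 for day 4 minus 2, 47 for day 7 minus 4 and 2 by the F test, bright genes 1 at day 4, 8 at day 7, 42 for day 7 minus 4 and 3 by the F test, no centring 8 at day 7, 10 for day 7 minus 4 and 0 by the F test, scaling 4 at day 4, 1 for day 4 minus 2 and 68 for day 7 minus 4, 1 probe set per gene 8 at day 2 and 1 for day 4 minus 2, the block 4 at day 2, 2 at day 7 and 0 by the F test, and robust variance 0 by the F test. With 1 probe set per gene 5 lists passed at day 4. For days 2, 4 and 7, the mean, day 4 minus 2, day 7 minus 4 and day 7 minus 2, camera with an estimated correlation called 0, 0, 2, 0, 0, 0 and 1 lists, and fry 2, 3, 2, 4, 3, 3 and 1. Among bright genes the correlations of day 2 with days 4 and 7 were 0.0669 and 0.177.

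Leaving out a sample gave 0 to 1 genes at day 2, 0 to 5 at day 4, 1 to 19 at day 7, 0 to 5 for the mean, 0 to 1 for day 4 minus 2, 0 to 4 for day 7 minus 4, 0 to 1 for day 7 minus 2 and 0 to 2 by the F test. It gave 0 to 1, 0 to 3 and 0 to 45 probe sets at days 2, 4 and 7, and 558 to 663 at day 1. In the variance trend fit it gave 0 to 12, 0 to 6 and 0 to 12 genes at days 2, 4 and 7, 11 to 40 for the mean, 0 to 1, 0 to 24 and 0 to 1 for the differences in the same order, and 0 to 6 by the F test. The lists called were 5 to 11 at day 7 and 5 to 16 for day 7 minus 2. With 1 array per day the correlations lay between -0.0216 and 0.0395 (days 2 and 4), -0.0749 and 0.120 (2 and 7) and -0.101 and 0.0271 (4 and 7).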

Other observations

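The variance trend fit, chosen after seeing the data, called 26 genes over days 2, 4 and 7 beyond the 8 already described. Among those higher were Lbp, which binds bacterial lipopolysaccharide, at 1.16, Lcn2 at 1.19, Igfbp1 at 1.32, Cd36 at 1.08, C4bpa at 0.50, Serpina10 at 0.45 and Apob at 0.38. Atp5if1 was at 1.47. Among those lower were the drug-metabolizing enzymes Fmo1 at -0.69, Ces1d at -0.69 and Gstm2 at -0.42, the liver transcription factors Foxa2 at -0.74 and Onecut1 at -1.32, the calcium-dependent membrane protein Anxa2 at -1.01, the kinase Map2k6 at -1.05, the mitochondrial carrier Slc25a30 at -1.28 and the kinetochore gene Spc24 at -1.56. Cela1, a member of the exocrine pancreas list, was also lower, at -0.46, while that list rose. Of the 34 genes, 20 had the same sign in 9 of 9 samples. Leaving out 1 sample gave between 11 and 40 calls, which held between 10 and 26 of the 34. Every one of the 34 kept its sign, which is little support, as the genes were picked by passing in the same samples.

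Of the 33 lists, 11 were called in none of the 7 comparisons of the 12-array fit, with a lowest adjusted p of 0.0643 and day medians between -0.17 and 0.24. They are gluconeogenesis and glycolysis, heat shock chaperones, endoplasmic reticulum stress, interferon response, cytokine and chemokine signalling, and the markers of neutrophils, lymphocytes, cholangiocytes, skeletal muscle, adipose tissue and skin. Of these, the cytokine list passed at day 7 in the variance trend fit (median 0.13, adjusted p = 0.024). The cytokine list was not among the 2 that passed at day 7 with an estimated correlation in the 12-array fit. Adjusted over the list alone, 5 of its 56 members rose and 3 fell at day 2, and 8 rose and 2 fell over days 2, 4 and 7. The 18 spike-in probe sets had medians from -0.66 in sample 1 of day 4 to 0.41 in sample 3 of day 2, relative to the array median.

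Signs of whole arrays were turned at random to ask whether the mean of days 2, 4 and 7 could arise by chance, with 100 of 256 patterns drawn and the real one included. The 8 genes of the 12-array fit were reached by 1 of 100 patterns, with 3 genes in the highest other. The 34 genes of the variance trend fit were reached by 1 of 100, with 27 in the highest other. No other drawn pattern thus reached either count in these fits. That speaks against no effect in any gene. It does not show that all 8 or all 34 genes changed, as turned signs alone gave up to 27. The first count is 0 to 5 when a sample is left out, 1 with the block for sample number and 4 without day 1. The second is 11 to 40 when a sample is left out, 23 with the block and 24 with 1 probe set per gene, the last 2 below the 27 of a turned pattern. No sign patterns were run for those other fits. The 7 lists were reached by 25 of 100 patterns, with 12 in the highest other, so that chance cannot be excluded for the number of lists.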
